A study of Mus musculus with 6 samples.

How the data were processed

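Poly(A)-selected RNA from ureters of 2-week-old mice was sequenced as strand-specific libraries, 3 labelled wild type and 3 labelled Col17a1 knockout, per the labels' protocols. The authors used FastQC 0.12.1, Trimmomatic 0.38 and HISAT2 2.1.0 with the mouse genome build GRCm39, per the submitters' processing notes. The counting tool, its strand setting and the gene annotation are not given in the sources used here, so values of genes that overlap or share near-identical copies are uncertain. The authors deposited a table of whole-number read counts and a table of length-scaled transcript abundance (TPM), each for the same 57186 genes and 6 libraries. Within a tolerance of 0.001 in natural log, the deposited TPM values were the counts divided by 1 fixed length per gene in 100% of the genes with a count in every library. Columns were assigned to samples by the library name that the labels give for each sample, and replicates are numbered as in the sample titles.

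Gene symbols were found for 51880 of the 57186 gene identifiers in a mouse table of an older build, used for names and chromosomes only, and 5306 had none. Identifiers without a symbol held 0.779% to 1.30% of the counts and stayed in the tests. Total counts ran from 15942743 to 18716799 per library. A count of 0 allows up to 3 counts, or 0.160 to 0.188 CPM, as counting error alone. Mitochondrial genes held 7.93% to 16.9% of the counts and TMM scaling factors ran from 0.843 to 1.08.

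The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, robust, R 4.3.3) on the deposited counts, with filterByExpr, TMM scaling and group as the only term, and a Benjamini-Hochberg adjusted p under 0.05. It took in 18305 genes and the common biological coefficient of variation was 35.6%. CPM values are scaled by TMM, and log2 CPM uses a prior count of 2. Before the data were examined, 31 gene lists with 468 symbols were fixed, and 409 of these genes passed the filter. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, then with an estimated correlation, and with fry, each adjusted over the 31 lists. Fry's directional test asks whether the genes of a list move, on balance, one way, and its mixed test whether they change in either direction. The level of a list in a library is the mean log2 CPM of its measured genes, compared between groups by an exact two-sided permutation test over the assignments of the 6 libraries.

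The genes named were set by a rule fixed at the same time. It takes Col17a1, 12 fixed urothelial and hemidesmosome genes, up to 10 genes each of the largest rises and falls past the threshold with no overlap between groups and a mean of at least 1 CPM, and up to 4 per list. Where none pass, it takes the 10 genes with the smallest p, leaving out predicted and unnamed genes, antigen receptor segments and sex-linked genes. Other list members, single genes of other tissues and Entpd4 were chosen as examples after their values were seen.

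Libraries of a group were compared before averaging. No pair was identical, and each pair within a group differed by more than sampling noise (chi-square per degree of freedom 15.2 to 113). Counts simulated from the means, library sizes and dispersions of the 6 libraries, with 100 genes changed 2-fold and 100 changed 4-fold among 18020 genes tested, returned 10% and 62% of them with 10 false calls. With a dispersion of 0.01 in every gene 97% and 100% came back. In a further simulation a smooth muscle list raised 1.5-fold was called by camera and 0 of the 30 others were. Genes were drawn independently there, with 1 dispersion for all, while estimated correlations within lists of the data reached 0.873 (B cells). The simulation therefore does not show how often camera passes unchanged lists in these data. In the 9 other splits of the libraries into 3 and 3, which mix the labels, camera passed 8 to 14 lists.

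Alternatives fixed before the data were examined covered other scalings, filters, tests (DESeq2 1.42.0, limma-voom, limma on log2 TPM with pseudocounts of 1 and 0.1), thresholds, a replicate block and each library left out in turn. After the data were seen, a fit without the libraries labelled WT 2 and Col17a1-KO 1 was added, because both hold male accessory gland transcripts, and the planned fit without WT 2 was picked out as the reading for the pan-epithelial list. Figures were drawn with matplotlib 3.10.9. Libraries were never regrouped by their level of Col17a1.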

Results

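Gene expression was measured by bulk RNA-seq in ureters of 2-week-old mice, the tubes of smooth muscle lined by urothelium that carry urine from kidney to bladder. The labels gave 6 libraries in 2 groups, 3 labelled wild type (WT) and 3 labelled Col17a1 knockout (KO). Col17a1 encodes collagen XVII, a transmembrane collagen of hemidesmosomes, which anchor basal epithelial cells to the basement membrane. The stated purpose of the series was to learn how this collagen acts in the upkeep of the urothelium. Total counts per library were 15942743, 18000829 and 18716799 in the libraries labelled WT 1, 2 and 3, and 16941479, 18108193 and 16938021 in those labelled Col17a1-KO 1, 2 and 3. The labels do not say whether a library came from 1 animal or from several. The p-values of single genes and of the permutation tests therefore rest on the spread between these libraries. Camera with its preset correlation compares the genes of a list with all other genes and treats them as nearly independent. Its p-values do not measure how well the difference of a list repeats between libraries.

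The targeted gene was read first, as a check of the labels. Col17a1 (ENSMUSG00000025064) had counts of 87, 741 and 45 in the libraries labelled WT 1, 2 and 3, and of 104, 1189 and 1437 in those labelled Col17a1-KO 1, 2 and 3. In counts scaled to library size (CPM) the WT-labelled libraries held 15.5 ± 19.8 and the KO-labelled libraries 50.8 ± 40.0 (mean ± SD, n = 3 each). The transcript thus went against the labels: in 8 of the 9 pairs of a KO-labelled and a WT-labelled library, the KO-labelled library held more. The difference was within the spread of the libraries, with a log2 fold change of 1.70 (SE 1.10) and an adjusted p of 0.998 in edgeR's quasi-likelihood test. The files give 1 count per gene, so reads over a deleted part of the gene cannot be told from reads over the rest, and the labels do not describe the allele. Each direction below is drawn from the labels, which Col17a1 did not bear out, and each library is named as labelled.

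Other genes of the hemidesmosome varied far less in bulk RNA, which does not part urothelium from other cells that may make them. Itga6 and Itgb4, the integrin subunits of the hemidesmosome, had 182 ± 59.3 and 82.6 ± 27.3 CPM in the WT-labelled libraries and 179 ± 56.1 and 68.5 ± 4.94 CPM in the KO-labelled libraries. Dst and Plec, which link the integrin to keratin filaments, had 350 ± 44.2 and 242 ± 48.5 CPM against 376 ± 50.3 and 232 ± 14.5 CPM. None of these 4 genes passed the test (adjusted p 0.998 each in edgeR), and the signs of Itga6 and Plec turned under other scalings. Over the 12 measured genes of the hemidesmosome and epithelial basement membrane, 10 had lower means in the KO-labelled libraries, with an adjusted p of 0.122 in camera, a test of a list against all other genes. That p was 0.708 with an estimated correlation. With each library left out it ran from 0.00280, without the library labelled WT 3, to 0.915, without WT 1, where the direction turned. With library size only 5 of the 12 genes lay higher, and on log2 TPM, where the median over all genes lay at 0.14 to 0.16, 6 of 12 did.

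**Figure D1:**
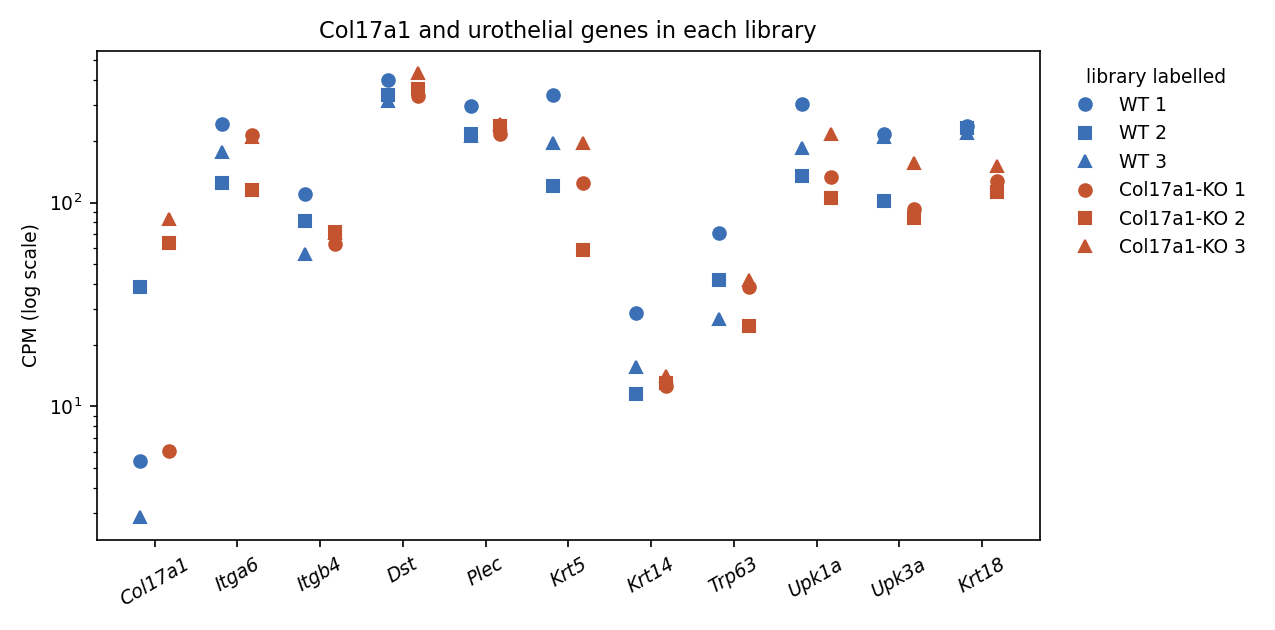
CPM on a log scale of Col17a1 and 10 epithelial and hemidesmosome genes in each of the 6 libraries. Blue symbols are libraries labelled WT, orange symbols those labelled Col17a1-KO, and the symbol shape gives the replicate number. Col17a1 spans 2.86 to 83.1 CPM and is high in 1 library labelled WT and in 2 labelled Col17a1-KO, while Krt18 lies lower in all 3 libraries labelled Col17a1-KO.

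Across all genes, the comparison of KO-labelled with WT-labelled ureters called 0 genes higher and 0 lower among 18305 tested. The smallest adjusted p in edgeR was 0.998. At an unadjusted p under 0.05 there were 457 genes, 298 higher and 159 lower, where 915 would be reached by chance. DESeq2 and limma-voom also called 0 genes, with 756 and 275 at an unadjusted p under 0.05. In 1118 genes, 6.11% of those tested, all 3 libraries of one label lay above all 3 of the other, and chance gives 10%. Counts simulated with the dispersions of these 6 libraries gave back 10% of genes changed 2-fold and 62% of genes changed 4-fold, so most 2-fold changes were not detectable here.

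The 10 genes with the smallest p, none of which passed the threshold, included several epithelial genes. Krt18, a keratin of simple and luminal epithelia, had 229 ± 9.13 CPM in the WT-labelled and 130 ± 18.99 CPM in the KO-labelled libraries, a log2 fold change of -0.81 (SE 0.19). Spint1 and Spint2, inhibitors of epithelial serine proteases, had 50.8 ± 5.13 and 117 ± 52.5 CPM against 30.7 ± 3.53 and 50.7 ± 3.34 CPM. Elf3, an epithelial transcription factor, had 23.8 ± 3.44 against 13.6 ± 1.60 CPM. Cyp2f2, a cytochrome P450, had 21.9 ± 1.92 against 11.8 ± 0.918 CPM, Serinc2 38.1 ± 7.22 against 19.1 ± 3.42 CPM, and Hoxb8 33.5 ± 11.2 against 13.3 ± 3.29 CPM. Fcna, a ficolin, and Sema3d, a secreted semaphorin, lay the other way, with 7.22 ± 1.61 and 8.14 ± 1.89 CPM in the WT-labelled and 15.7 ± 3.70 and 16.4 ± 2.13 CPM in the KO-labelled libraries. Entpd4b had 16.2 ± 4.59 against 3.81 ± 2.54 CPM, a value that is uncertain because the near-identical Entpd4 was counted at 0 or 1 in every library. Unadjusted p-values of these genes ran from 0.00219 to 0.00572 in edgeR, and the adjusted p was 0.998 for each.

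Genes shared by most epithelial cells lay lower together in the KO-labelled libraries. All 19 measured pan-epithelial genes had a lower mean there, and the mean level of the list was 5.78 ± 0.50 log2 CPM in the WT-labelled and 4.93 ± 0.32 in the KO-labelled libraries (SD, n = 3 each). An exact permutation test of these levels gave a p of 0.1, the smallest possible, and an adjusted p of 0.775. The smooth muscle list had the same values, other lists shared the adjusted p, and none of the 31 lists went below it. Cldn7, a tight junction claudin, had 20.8 ± 12.2 against 7.02 ± 2.06 CPM, Krt8 231 ± 39.9 against 145 ± 33.5 CPM, and Epcam, an epithelial adhesion molecule, 49.5 ± 52.7 against 15.1 ± 5.83 CPM. At the gene level 0 members passed over all genes tested, and 4 (Krt18, Spint1, Spint2 and Cldn7) passed adjusted over the list alone. Camera with its preset correlation gave the list an adjusted p of 4.4e-17, and the adjusted p was 0.512 with an estimated correlation. The same test also passed this list in 4 of the 9 splits of the libraries that mix the labels, at an adjusted p down to 1.7e-08. The library labelled WT 2 held the highest level, 6.31 log2 CPM, and also held transcripts of male accessory glands, with 19231 counts of Svs4 and 5968 of Svs2, seminal vesicle secretory genes that had 0 or 1 count elsewhere. Without it the adjusted p of the list was 9.2e-10 and the difference in level was -0.59 log2, against -0.85 with all 6 libraries. Epcam rested on that library, with 110 CPM there against 20.2 and 18.0 in WT 1 and WT 3, and its log2 fold change went from -1.72 (SE 0.71) to -0.34 (SE 0.34) without it. Krt18 stayed at -0.81. The library labelled Col17a1-KO 1 also held a gland transcript, with 644 counts of Pbsn, a prostate secretory gene, against 400 in WT 2. Without both libraries, a fit chosen after the data were seen, the adjusted p of the list in camera was 6.5e-09. All 19 genes still had a negative log2 fold change there, with a mean of -0.65 against -0.97 with all 6 libraries.

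**Figure D2:**
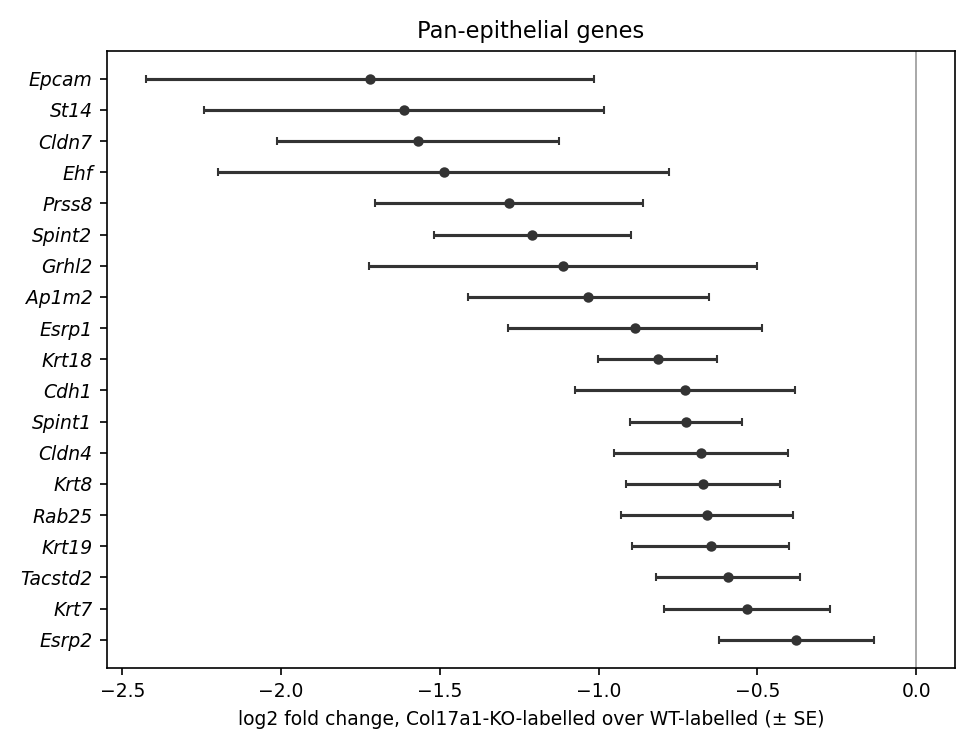
Log2 fold change with its standard error for the 19 measured pan-epithelial genes, libraries labelled Col17a1-KO over those labelled WT, from edgeR with n = 3 per group. Every point lies below 0, from -1.72 for Epcam to -0.38 for Esrp2, and none passed the threshold over all genes. Without the library labelled WT 2 the largest fall is that of Cldn7 (-0.98), and Epcam is at -0.34.

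Superficial markers mostly lay lower as well. Of 12 genes on the list for superficial urothelium, the umbrella cells that face the urine, 11 had lower means in the KO-labelled libraries. Pparg lay higher, at 199 ± 24.0 CPM there against 163 ± 36.8 in the WT-labelled libraries. Which cells made these genes was not measured, so the count does not show a loss of umbrella cells. Among the uroplakins, which form plaques in the apical membrane, Upk2 had 84.0 ± 36.8 against 44.4 ± 21.0 CPM, Upk3a 176 ± 64.5 against 111 ± 39.9, Upk1a 208 ± 87.8 against 151 ± 57.6 and Upk1b 220 ± 106 against 198 ± 49.9. Krt20, a keratin of umbrella cells, had 63.0 ± 24.0 against 48.3 ± 6.36 CPM. On log2 TPM, where the median over all genes lay at 0.14 to 0.16, 4 of the 12 genes lay higher. The superficial list had an adjusted p of 0.00106 in camera and of 0.512 with an estimated correlation. This call was lost without the library labelled WT 1 (adjusted p 0.430) and without that labelled Col17a1-KO 2 (0.0511).

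The basal cell list did not pass with all 6 libraries. Krt5 and Krt14, keratins of basal cells, had 218 ± 109 and 18.6 ± 8.88 CPM in the WT-labelled libraries against 127 ± 68.7 and 13.3 ± 0.773 CPM in the KO-labelled libraries. Trp63, a transcription factor of basal cells, had 46.3 ± 22.3 against 35.0 ± 8.82 CPM. The basal list had an adjusted p of 0.116 in camera, and of 0.676 with an estimated correlation. Left-out libraries moved it from 0.0717 to 0.860, and its direction turned without WT 1. It was 0.0496 without both WT 2 and Col17a1-KO 1, a fit chosen after the data were seen. Read against the pan-epithelial genes of the same library, the basal list lay 0.61 log2 higher in the KO-labelled libraries, the hemidesmosome list 0.68 higher and the superficial list 0.46 higher. Exact two-sided permutation tests gave p-values of 0.1, 0.1 and 0.5, and of 0.3, 0.4 and 0.9 with medians in place of means, and 0.1 is the smallest that 3 libraries against 3 allow. These differences rested largely on the library labelled WT 2, and without it they were 0.33, 0.39 and 0.0274.

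Tight junction and desmosome genes lay lower in 17 of 18 members, among them Dsp, the desmosomal linker to keratin, with 66.4 ± 24.7 against 40.4 ± 9.83 CPM. On log2 TPM, where the median over all genes lay at 0.14 to 0.16, 5 of the 18 lay higher. The list had an adjusted p of 4.9e-04 in camera, and of 0.512 with an estimated correlation. The call was lost without the library labelled WT 2 (adjusted p 0.158). Of the 9 measured squamous and wound keratin and cornified envelope genes, 3 had higher means and 6 lower (adjusted p 0.558). That list passed as lower without the library labelled Col17a1-KO 3 (0.00731), and with no low-count filter (0.0394), where 5 of 17 genes lay higher.

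Among smooth muscle genes, 15 of 16 had lower means in the KO-labelled libraries. Whether they came from the ureter wall or from other tissue in the libraries cannot be told from bulk RNA. Des, the intermediate filament protein desmin, had 162 ± 40.6 against 110 ± 20.7 CPM, Mylk, the myosin light chain kinase, 1166 ± 219 against 823 ± 234, and Acta2, smooth muscle actin, 1260 ± 154 against 1052 ± 93.8. On log2 TPM 5 of the 16 genes lay higher and the mean log2 fold change went from -0.29 to -0.11 and -0.10. The median over all genes also moved there, from -0.02 to 0.14 and 0.16, so this shift is not particular to the list. The list level was 7.70 ± 0.16 against 7.42 ± 0.12 log2 CPM (SD, n = 3 each), with a p of 0.1 and an adjusted p of 0.775 in an exact permutation test. Its adjusted p was 6.3e-05 in camera and 0.512 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone.

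All 20 mitosis genes and all 15 macrophage and myeloid genes had higher means in the KO-labelled libraries. Top2a, a topoisomerase of dividing cells, had 15.5 ± 1.16 against 30.3 ± 13.7 CPM and Ccnb1, cyclin B1, 2.83 ± 0.653 against 5.79 ± 2.51. C1qa, a complement gene of macrophages, had 27.1 ± 2.12 against 46.1 ± 11.9 CPM and Csf1r, the receptor for macrophage growth factor, 54.7 ± 12.7 against 92.5 ± 37.7. The mitosis list had its highest level in the library labelled Col17a1-KO 3 (3.73 log2 CPM) and the macrophage list in that labelled Col17a1-KO 2 (5.18). Adjusted p-values in camera were 3.3e-09 and 2.5e-10, each 0.512 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Without Col17a1-KO 3, 15 of the 20 mitosis genes lay higher and the difference in level went from 0.58 to 0.26 log2 (adjusted p 0.00731). Without Col17a1-KO 2, 12 of the 15 macrophage genes lay higher and the difference went from 0.77 to 0.38 (adjusted p 6.4e-05). Of 20 DNA replication genes 15 had higher means, with an adjusted p of 0.0102 in camera and of 0.512 with an estimated correlation. That call was lost without the library labelled Col17a1-KO 3 (adjusted p 0.194) and without WT 2 (0.0977).

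Lymphocyte, neutrophil and skeletal muscle genes stood high in a single library. The library labelled Col17a1-KO 2 held 315 counts of Cd3e, a T cell receptor component, where the others held 2 to 15. It held 3893 counts of Ighm, the immunoglobulin M heavy chain, against 158 to 773, and 1350 of S100a8, a neutrophil gene, against 8 to 35. It also held 1774 counts of Acta1, skeletal muscle actin, against 49 to 353, and 655 of Dbh, an enzyme of noradrenaline synthesis, against 6 to 187. All 10 B cell, 5 T and NK cell and 7 skeletal muscle genes measured, and 9 of 10 neutrophil and mast cell genes, had higher means in the KO-labelled libraries. Camera gave adjusted p-values of 3.3e-05, 0.00947, 0.0223 and 0.00904, which were 0.512, 0.534, 0.676 and 0.564 with an estimated correlation. Without that library they were 0.133, 0.644, 0.646 and 0.396. The calls were also lost for neutrophils without WT 2 (adjusted p 0.0886) or WT 3 (0.243), and for skeletal muscle without WT 1 (0.113) or WT 2 (0.260) and, with all 6 libraries, on log2 TPM with a pseudocount of 0.1 (0.0640). Of 11 inflammatory genes 8 had higher means, among them the cytokine Il33 with 10.51 ± 0.584 against 20.02 ± 7.71 CPM. Their list had an adjusted p of 0.00448, of 0.512 with an estimated correlation and of 0.133 without the library labelled Col17a1-KO 2.

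**Figure D3:**
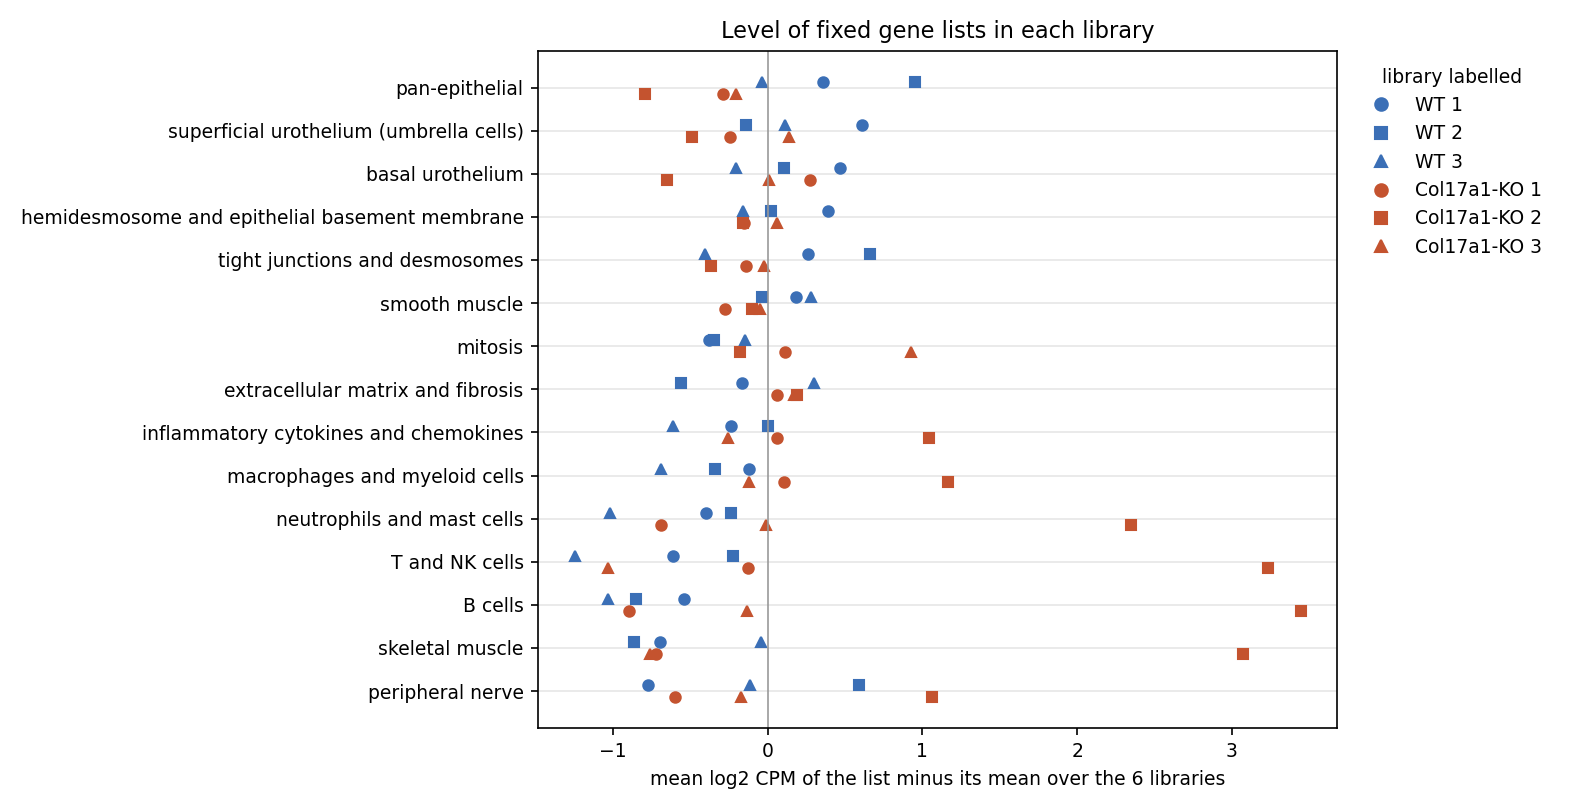
Mean log2 CPM of 15 gene lists in each of the 6 libraries, minus the mean of the list over all 6; blue symbols are libraries labelled WT, orange those labelled Col17a1-KO, and the symbol shape gives the replicate number. The library labelled Col17a1-KO 2 stands apart in the T and NK cell, B cell, neutrophil and skeletal muscle lists, and the pan-epithelial list is lower in all 3 libraries labelled Col17a1-KO.

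Of 16 Hedgehog and Bmp genes of the ureter 14 had lower means, among them Id2, a Bmp target, with 104 ± 12.6 against 75.9 ± 18.2 CPM. Of 15 Wnt genes 11 had lower means, among them Nkd1, a Wnt target, with 57.9 ± 20.4 against 31.6 ± 4.30 CPM. Of 20 extracellular matrix and fibrosis genes 16 had higher means, among them Fn1, fibronectin, with 448 ± 198 against 643 ± 173 CPM. Of 18 sterol and fatty acid synthesis genes 14 had lower means. Adjusted p-values in camera were 0.00809, 0.00271, 0.00745 and 0.0422, and 0.512, 0.512, 0.512 and 0.676 with an estimated correlation. The Hedgehog call was lost without the libraries labelled WT 1 (adjusted p 0.0590), WT 2 (0.0977) or Col17a1-KO 2 (0.438), and the Wnt call without WT 2 (0.0732) or Col17a1-KO 2 (0.0535). The matrix call was lost without WT 2 (0.566) or Col17a1-KO 3 (0.0686), and the sterol call without WT 1 (0.210), WT 2 (0.182), Col17a1-KO 1 (0.635) or Col17a1-KO 2 (0.396).

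The other lists did not pass at the settings of the main test. Adjusted p-values in camera were 0.127 for the interferon response, 0.130 for fibroblasts, 0.383 for peripheral nerve, 0.550 for p53 targets and for endothelium, and 0.558 for the unfolded protein response. They were 0.626 for adipocytes and for erythroid cells, 0.675 for adrenal, gonad and genital tract, 0.750 for immediate early and heat shock genes, 0.779 for kidney and 0.828 for hypoxia and glycolysis. The kidney list passed with no low-count filter (0.00502), as lower, with 3 of 15 genes higher. With 1 library left out, calls were gained for fibroblasts without Col17a1-KO 2 (4.4e-06), erythroid cells without WT 1 (0.00136), adipocytes without WT 2 (0.0484), and peripheral nerve and adrenal and gonad without Col17a1-KO 1 (0.0331 and 0.0489). The interferon list passed without WT 1 (0.0319), Col17a1-KO 1 (0.0489) or Col17a1-KO 2 (0.00788), and the immediate early list without Col17a1-KO 3 (3.8e-04) and, turned to lower, without Col17a1-KO 2 (0.00788). Adipocyte genes were abundant under both labels, with Lpl, lipoprotein lipase, at 2928 ± 959 and 2306 ± 534 CPM. The level of the adipocyte list was 9.35 ± 0.50 log2 CPM in the WT-labelled and 9.30 ± 0.18 in the KO-labelled libraries. The smooth muscle list lay below it, at 7.70 and 7.42. Of the 31 lists, 16 passed with the preset correlation and 0 with an estimated correlation or by fry. Calls for 4 of the 16 lists (pan-epithelial, smooth muscle, mitosis and macrophages) held when each library was left out in turn. In the 9 splits that mix the labels, the smooth muscle, mitosis and macrophage lists passed in 2, 7 and 6.

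All 6 libraries carried transcripts of the Y chromosome, with 1606 to 2722 counts of Ddx3y and 3 to 16 counts of Xist, the RNA of the inactive X chromosome. A planned comparison of the chromosomes of changed genes had no genes to work on, since 0 genes passed.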

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

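The fit without the libraries labelled WT 2 and Col17a1-KO 1 was chosen after the data were seen, and the other settings before. Under all 21 planned settings and the added one, 0 genes passed in either direction, with 184 to 759 at an unadjusted p under 0.05. Col17a1 kept a positive log2 fold change, from 1.15 without Col17a1-KO 3 to 4.15 in the added fit, where its adjusted p was 0.285. That fit left out the WT-labelled library with the most Col17a1 (WT 2, 38.4 CPM) and the KO-labelled one with the least (Col17a1-KO 1, 6.07). The larger value there follows from that choice and lends no further support. Of 418 values of the other named genes 402 kept their sign. Exceptions with all 6 libraries were Itga6 at 0.0186 with upper-quartile scaling, 0.0477 with library size only, and 0.15 and 0.15 on log2 TPM with pseudocounts of 1 and 0.1. Plec was at 0.0007, 0.13 and 0.14 in the last 3 of these, and Upk1b at 0.10 and 0.11 on log2 TPM, where the median over all genes lay at 0.14 and 0.16 against -0.02. Leave-one-out ranges were -0.67 to 0.0393 for Trp63, -0.39 to 0.31 for Upk1b, -0.23 to 0.25 for Itga6, -0.47 to 0.0037 for Itgb4, -0.14 to 0.12 for Plec and -0.0134 to 0.21 for the log2 fold change of Dst. Lists past the threshold numbered 16 in the reported fit, 18 with no filter, 15 on log2 TPM with a pseudocount of 0.1 and in the added fit, 9 to 18 with each library left out, but 0 with an estimated correlation, 0 by fry's directional and 0 by its mixed test. Of 558 list values 480 kept direction and call, 36 turned, 28 lost and 14 gained a call, among them squamous genes with no filter (0.0394), and basal (0.0496) and peripheral nerve (0.00817) in the added fit, which lost tight junctions (0.233), extracellular matrix (0.708) and sterol synthesis (0.751). Turned adjusted p-values were 0.00502 for kidney and 0.954 for adrenal and gonad with no filter, and 0.995 for immediate early genes with library size only. On log2 TPM they were 0.807 and 0.741 for immediate early genes, 0.470 and 0.927 for kidney and 0.989 for hypoxia, and in the added fit 0.391 for immediate early genes, 0.708 for fibroblasts, 0.182 for endothelium and 0.443 for erythroid cells. Lists that turned in at least 1 leave-one-out fit had adjusted p-values there of 0.00280 to 0.915 for hemidesmosome, 0.0717 to 0.860 for basal, 0.00788 to 0.556 for interferon, 0.0721 to 0.932 for hypoxia, 0.302 to 0.973 for unfolded protein, 3.8e-04 to 0.948 for immediate early, 4.4e-06 to 0.991 for fibroblasts, 0.0683 to 0.753 for endothelium, 0.501 to 0.991 for kidney, 0.0484 to 0.960 for adipocytes, 0.0331 to 0.896 for peripheral nerve, 0.00108 to 0.646 for skeletal muscle, 0.00136 to 0.948 for erythroid and 0.0489 to 0.891 for adrenal and gonad. The cause was not tested for any of these. Relative to pan-epithelial genes, the basal, superficial and hemidesmosome lists stayed positive but went from 0.61, 0.46 and 0.68 to 0.33, 0.0274 and 0.39 without WT 2, and to 0.87, 0.53 and 0.78 with medians (exact permutation p 0.3, 0.9 and 0.4). With the replicate number as a block 0 genes and 16 lists passed. Deviations of same-numbered libraries correlated at 0.102, 0.300 and 0.070, and not every library correlated best with its own number. Whether the numbers pair the libraries stays open, since deviations from a mean of 3 libraries depend on one another. A sex covariate was not run because all libraries carry Y-linked transcripts.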

Other observations

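Transcripts typical of other tissues were present in several libraries, and their source was not settled. The library labelled WT 2 held 4269 counts of Svs5 and 400 of Pbsn, a prostate secretory gene, and the library labelled Col17a1-KO 1 held 644 of Pbsn with 0 of Svs4. The library labelled Col17a1-KO 2 held 777 counts of Ccr7 and 594 of Cxcl13, genes of organised lymphoid tissue, against 6 to 15 and 8 to 51 elsewhere. It also held 470 of Th, an enzyme of catecholamine synthesis, against 5 to 141, and 1336 of Ckm, muscle creatine kinase, against 138 to 401. Nnt, a mitochondrial transhydrogenase, had 0 to 8 counts in the 6 libraries, and the series gives the background as C57BL/6N. Each of these genes was chosen after its values were seen.

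The most alike pair of libraries crossed the labels. The libraries labelled WT 1 and Col17a1-KO 3 had a Pearson correlation of 0.986 across genes, which are not independent replicates, yet differed 15.1-fold in Col17a1. Only 4 of 18305 genes differed as much between them (Col17a1, Trmt9b, Aqp2 and Wsb2-ps). The splits of the libraries were planned, and the other tests below were chosen after the results were seen.

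Col17a1 did not separate the labelled genotypes. Read against the mean of the hemidesmosome list, it spanned 4.59 log2 units over the 6 libraries, beyond the widest list member at 0.963. Bulk RNA does not show which cells made those genes, so this list is an uncertain gauge of urothelium. The basal list, used first, gave 4.86 against 4.36. Both spans argue against the amount of urothelium as the whole cause. Libraries exchanged or mislabelled could give such values, but the 8 of 9 pairs that go against the labels are the pattern itself and no support for it. Right labels with an allele that still makes the transcript cannot be told apart from this. Such an allele would have to leave more transcript in Col17a1-KO 2 and 3 than in any WT-labelled library. Those 2 libraries held 63.3 and 83.1 CPM, against 5.38, 38.4 and 2.86 in WT 1, 2 and 3, while Col17a1-KO 1 held 6.07. The smaller within-group span was 3.52 against 0.963 with the hemidesmosome list, but 3.39 against 4.15 with the basal list. Krt15 sets the basal bound (1.12 without it). It had 277 and 319 counts in the libraries labelled WT 2 and Col17a1-KO 1, which hold Pbsn, and 12 to 25 elsewhere. Without Krt15 both lists put Col17a1 beyond every member, but each within-group span rests on 1 library, WT 2 or Col17a1-KO 1. The hemidesmosome list was taken up after the basal result was seen, so the reading needs both, and no library was reassigned.

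Pan-epithelial genes lay lower in the KO-labelled libraries. Gland epithelium in the library labelled WT 2 may add to this: without it the difference was -0.587 log2, against summed SDs of 0.593, which neither removes the pattern nor sets it apart from the spread. A smaller share of urothelium in the KO-labelled libraries cannot be told apart either, since the falls of the superficial and pan-epithelial lists differed by 0.459, within summed SDs of 0.910 but over the SD of the KO-labelled libraries (0.161), and by 0.0274 without WT 2. An effect of genotype was not tested, because Col17a1 goes against the labels. Of the 10 splits of the 6 libraries, the real one gave 16 lists and the highest other 14, so 1 of 10 reached the real count. These 10 splits are too few for a share under 0.05. For genes the real split gave 0 and the highest other 0, which decides nothing, since every split reaches a count of 0. At an unadjusted p under 0.05 in edgeR, the real split gave 457 genes and the others 441 to 1692.

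Lymphoid, neutrophil, myeloid and skeletal muscle lists lay higher in the KO-labelled libraries. For the T and NK cell, neutrophil and skeletal muscle lists this rests on the library labelled Col17a1-KO 2: without it the largest of the 3 differences in size was 0.206 log2, a lower level of skeletal muscle genes and within the SD of the WT-labelled libraries (0.413 or more). Lymphoid tissue, ganglion and muscle in that library may be the source, but a change in the ureters sampled there would fall away with it too, so these cannot be told apart. For the B cell list the difference without it was 0.292 against an SD of 0.248, and for the macrophage list 0.376 against 0.288, so a wider difference stays open as well. B cells were set apart after a joint test with the other 3 lists gave no clear result, and an effect of genotype was not tested, because Col17a1 goes against the labels.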
